A study of Caenorhabditis elegans with 24 samples.

How the data were processed

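RNA of 24 samples of 50 4-cell embryos was amplified by 2 rounds of in vitro transcription, labelled with Cy3 and hybridised to 1 array per sample, per the labels' protocols. The worms had been fed Bacillus subtilis, and the 8 groups (2 strains, 2 generations, ancestors at 20 °C or 25 °C) held 3 samples each, which the series' design text calls separately collected. Nothing states that they came from separate cultures, so p-values measure the spread between these samples. Spot intensities were extracted by the authors with Agilent Feature Extraction 9.5.3.1, per the file headers: the processed intensity was background-subtracted and detrended within the array, and 2 scans of different sensitivity were combined. The other columns used, flags of 0 or 1 for spots well above background, saturated or non-uniform, come from the same deposited scanner output. The deposited series table holds log2 values. Its processing is not given in the sources used here. Every column held the same set of values with a median of 9.03, kept the order of the processed signal of its own array and matched no other array better, so the scale is log2 of the processed signal after a quantile type of normalization. It differed from quantile-normalized values computed here by a median of 0.0460, and how ties were treated is unknown.

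Control spots were left out, and spots marked as non-uniform or population outliers were set to missing (3 to 373 per array). Values were log2 of the processed signal minus the 75th percentile of the array. A probe was tested if it was well above background on every array of at least 1 group (11637 of 15208, of which 8391 probes of the array were so on all 24 arrays). Each gene had 1 probe, so no rule for several probes was needed. The array's probe names are WormBase gene IDs with a supplier's suffix, which is left off here. Of the 15208 IDs, 0 were found in the reference gene table given, so no gene is named and the 26 gene lists fixed beforehand, which use names, were not tested. The rule for named genes (the largest rises and falls past the threshold, for the 2 temperature effects only where all treated arrays lay on one side of their strain's control mean) was kept and limited to 2 IDs per direction.

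A linear model with a mean for each of the 8 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), and 11 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the genes of each contrast at 0.05. The fit held no term for slide or scan day, and all groups share one estimate of the spread per gene. On simulated arrays with the real genes' means and residual spread and 200 changed genes among 11637, the fit for grandparental temperature in both strains recovered 38.8% of the 1.5-fold, 53.7% of the 2-fold and 86.4% of the 4-fold changes, with 6.30% of its calls false, and the fit for parental temperature in both strains recovered 31.3%, 44.8% and 84.8%, with 5.31% false. The fit for parental temperature in N2 alone recovered 19.4%, 52.2% and 78.8%, with 9.91% false (11 of 111 calls), and made 1 call with no change simulated. The fit for strain at 20 °C had 4.84% false. Other single-strain fits were not simulated. The simulated values were independent, with no slide, scan day or floor in them, whereas the real arrays had a correlation within slides of 0.51. The recovered and false shares therefore need not hold for the real arrays. The score of the parental genes, the comparison of calls between strains and between scan days, and the alternatives without slide 9 or without the scan day of replicate 3 were chosen after the data were examined. The tests of the contrasts, the groups and the other alternatives were fixed before the data were examined.

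The files gave 14 slides and 3 scan days. Each scan day held 1 array of each group, and the replicate number was the scan day (replicate 2 was scanned first). All 4 replicate 3 arrays of the 25 °C groups were on 1 slide, called slide 9 here, with no 20 °C array beside them, and all 4 carry a spike-in note. On 3 of them (N2 and HC445 at 25 °C in generation 2, and N2 at 25 °C in generation 3) 1518, 1976 and 1653 dim probes were tied at the lowest processed value of the array, so low values there mark a floor. The alternatives were normexp background correction (offset 50) with quantile normalization, run on median spot intensities because the files hold no column of mean signals; quantile normalization of the processed signal; no filter on dim probes; the 8391 probes well above background on all arrays; slide as a random and as a fixed block; the replicate number as a block; array quality weights; leaving out the 6 arrays with a spike-in note; the deposited series values; and leaving out each array. The highest correlation between any 2 arrays was 0.991, so no 2 arrays held the same values. Figures were drawn with matplotlib 3.10.9.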

Results

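Messenger RNA of 4-cell embryos of the nematode Caenorhabditis elegans was measured on 24 one-colour oligonucleotide arrays, each hybridised with amplified RNA from a separately collected sample of 50 embryos. The 24 samples formed 8 groups of 3. Embryos came from the wild-type laboratory strain N2 or from HC445, a strain labelled as carrying a mutation in sid-1, which encodes a channel for double-stranded RNA in systemic RNA interference, and as possibly lacking haf-6, a half-molecule ABC transporter gene linked to RNA interference. In generation 2 the mothers had been reared at 20 °C or at 25 °C, and in generation 3 the mothers had been reared at 20 °C and the grandparents at 20 °C or at 25 °C. Of 15208 gene probes, 1 per gene, between 9109 and 13075 were well above background on an array, and the 75th percentile of the processed signal lay between 30282 and 45402. A probe entered the tests if it was well above background on every array of at least 1 group, which left 11637. The files and the reference table do not pair the probe IDs with gene names, so probes are given by ID, at most 2 in each direction of a comparison. The number of arrays, 3 per group, limits the precision of every value.

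The first question was which maternal mRNAs of the early embryo differed after the mothers had lived at 25 °C in place of 20 °C. Embryos of 25 °C mothers differed broadly from those of 20 °C mothers, in both strains. With both strains pooled, 1626 of 11637 genes passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), of which 634 rose and 992 fell. Changes of at least 2-fold were found for 270 of the genes that rose and for 503 of those that fell, and at least 4-fold for 43 and 137. The median log2 fold change was 0.86 among genes that rose and -1.01 among genes that fell. Genes of the middle level class, by mean signal over all arrays, made up most of the rises, 407 of 634, against 88 in the low class and 139 in the high class of 3879 genes each. The falls were 281 in the low class, 523 in the middle class and 188 in the high class.

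The rises of 2 probes are given by ID. For WBGene00012176 the normalised log2 signal (relative to the 75th percentile of the array) was -5.56 ± 0.98 (SD, n = 6) after 25 °C and -10.81 ± 0.40 (SD, n = 6) after 20 °C, where it was not well above background on any array, so that it was at least 10.5-fold higher after 25 °C (limma adjusted p = 1.15e-07). A bound of this kind sets the mean of the bright group against, per array, the lowest signal among probes well above background or the probe's own signal where that was higher. WBGene00001557 rose by 5.22 ± 0.81 (SE) on the log2 scale (limma adjusted p = 8.76e-05), from -9.07 ± 1.70 (SD, n = 6) to -3.85 ± 0.35 (SD, n = 6), and 3 of its 6 control arrays were well above background. WBGene00007448 fell (limma adjusted p = 0.0369), but only 1 of its 6 arrays of 25 °C mothers was well above background, so the size of its fall is not given. WBGene00022754 had a log2 fold change of -4.25 ± 1.29 (SE; limma adjusted p = 0.0293), with 4 of 6 such arrays well above background. Both varied widely among the 6 control arrays, with SDs of 3.40 and 2.85, and each fell short of the threshold in several refits. With slide as a fixed block all 4 of these probes fell short of it, the 2 rises with adjusted p of 0.0851 (WBGene00012176) and 0.0550 (WBGene00001557), the only refit in which these 2 did. Of the 992 falls, 45 included a value at the lowest processed signal of an array on which many dim probes were tied, so the depth of these falls is set partly by that floor. Of the 1626 genes, 1544 lay on one side of the mean of their own strain's control arrays on all 6 arrays of the 25 °C groups, on which they had also been picked.

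The balance of rises and falls depended on the scaling and, to a lesser degree, on 1 array. It also turned with slide as a fixed block, among 41 calls, but not with slide as a random block. Quantile normalization gave 1688 genes with 936 higher and 752 lower, and the series' own deposited values gave 937 higher and 756 lower. Without the N2 20 °C generation 2 array of replicate 3, which had the lowest array quality weight (0.277, the next lowest 0.651), 745 genes were higher and 830 lower. None of the 1626 genes changed sign under quantile normalization. The replicate number coincided with the day of scanning, and each of the 3 scan days held all 8 groups. With the scan day as a block the count was 2666 (1052 higher, 1614 lower), and within the days the fold changes had the sign of the pooled fit for 1566 of 1570 called genes with a value (replicate 1), 1605 of 1608 (replicate 2) and 1601 of 1602 (replicate 3). These genes were picked on the same arrays, which favours such agreement. Picked without the arrays of replicate 3, 973 genes passed, and 931 of the 962 with a value moved the same way on the arrays of replicate 3, with a median of 0.94 on the log2 scale. With slide as a random block the count was 1945 (770 higher, 1175 lower). With slide as a fixed block, which left 3 residual degrees of freedom, it was 41 (29 higher, 12 lower). The only slide that held a 25 °C and a 20 °C array of one strain in generation 2 gave the same sign for 1536 of 1591 genes, but its arrays were among those on which the genes were picked. The labels note or suspect a 10x spike-in concentration for 6 arrays, 5 of which were 25 °C arrays. Leaving them out left 1 array of N2 at 25 °C in generation 2, so the count of that refit is not given.

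Each strain taken alone gave fewer genes. In N2, 636 genes passed (247 rose, 389 fell), and in HC445, 591 genes (273 rose, 318 fell). With quantile normalization more rose than fell, 343 against 315 in N2 and 374 against 248 in HC445, and without the N2 20 °C array of replicate 3 the N2 genes were 316 higher and 259 lower. The N2 balance also turned with slide as a fixed block (161 higher, 153 lower) and without the scan day of replicate 3 (153 and 134), and that of HC445 with slide as a fixed block (2 and 0) and without its 20 °C array of replicate 2 (185 and 171). The N2 genes moved the same way in HC445 for 630 of 636, and the HC445 genes moved the same way in N2 for 588 of 591, with a median of 1.13 on the log2 scale in the direction of the HC445 change. No gene passed the limma test of the difference between the strains (strain by parental temperature), and 142 genes had an unadjusted p under 0.05, against 581.85 expected with no difference. The median SE of that difference was 0.44 on the log2 scale, against 0.22 for the pooled effect. Small differences between the strains could thus be missed, and the low count does not show that the strains respond alike. Across genes, which are not independent replicates, the fold changes of the strains had a Pearson r of 0.71, and effects taken from different scan days had r between 0.25 and 0.66. With the scan day as a block the counts were 1293 in N2 and 1130 in HC445. The HC445 count was 373 without the 20 °C array of replicate 1, 356 without that of replicate 2 and 360 without the 25 °C array of replicate 2.

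The second question was whether embryos whose mothers had been returned to 20 °C still differed according to the temperature of their grandparents. A small set of genes did, and most of these were lower, though not in every refit. With both strains pooled, 33 of 11637 genes passed the threshold (limma, Benjamini-Hochberg), of which 6 rose and 27 fell, with a median log2 fold change of 1.24 among the rises and -1.84 among the falls. The 6 rises and 13 of the falls belonged to the middle level class, 14 falls to the low class, and no call to the high class.

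WBGene00019611 rose most in embryos with 25 °C grandparents. Its log2 signal was -2.44 ± 0.40 (SD, n = 6) against -4.77 ± 0.81 (SD, n = 6), a 5.03-fold difference (limma adjusted p = 3.57e-05), and the 6 treated arrays were all above the control mean of their strain. After 25 °C mothers the same probe was 18.7-fold higher, so that generation 3 lay between the 25 °C level of generation 2 and the 20 °C level. WBGene00003593 rose by 1.95 ± 0.32 (SE) on the log2 scale (limma adjusted p = 0.00729), close to its change of 2.28 ± 0.32 (SE) after 25 °C mothers. WBGene00000720 fell furthest, with a log2 fold change of -3.62 ± 0.43 (SE; limma adjusted p = 9.02e-05), from -5.49 ± 1.31 to -9.11 ± 0.57 (SD, n = 6 each). WBGene00004997 had a log2 fold change of -3.26 ± 0.69 (SE; limma adjusted p = 0.0424) and lost the threshold in many of the refits, and 3 of its 6 treated arrays were well above background. Of the 27 falls, 4 included a value at the floor of an array. The 4 probes given by ID had all moved the same way after 25 °C mothers.

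**Figure D1:**
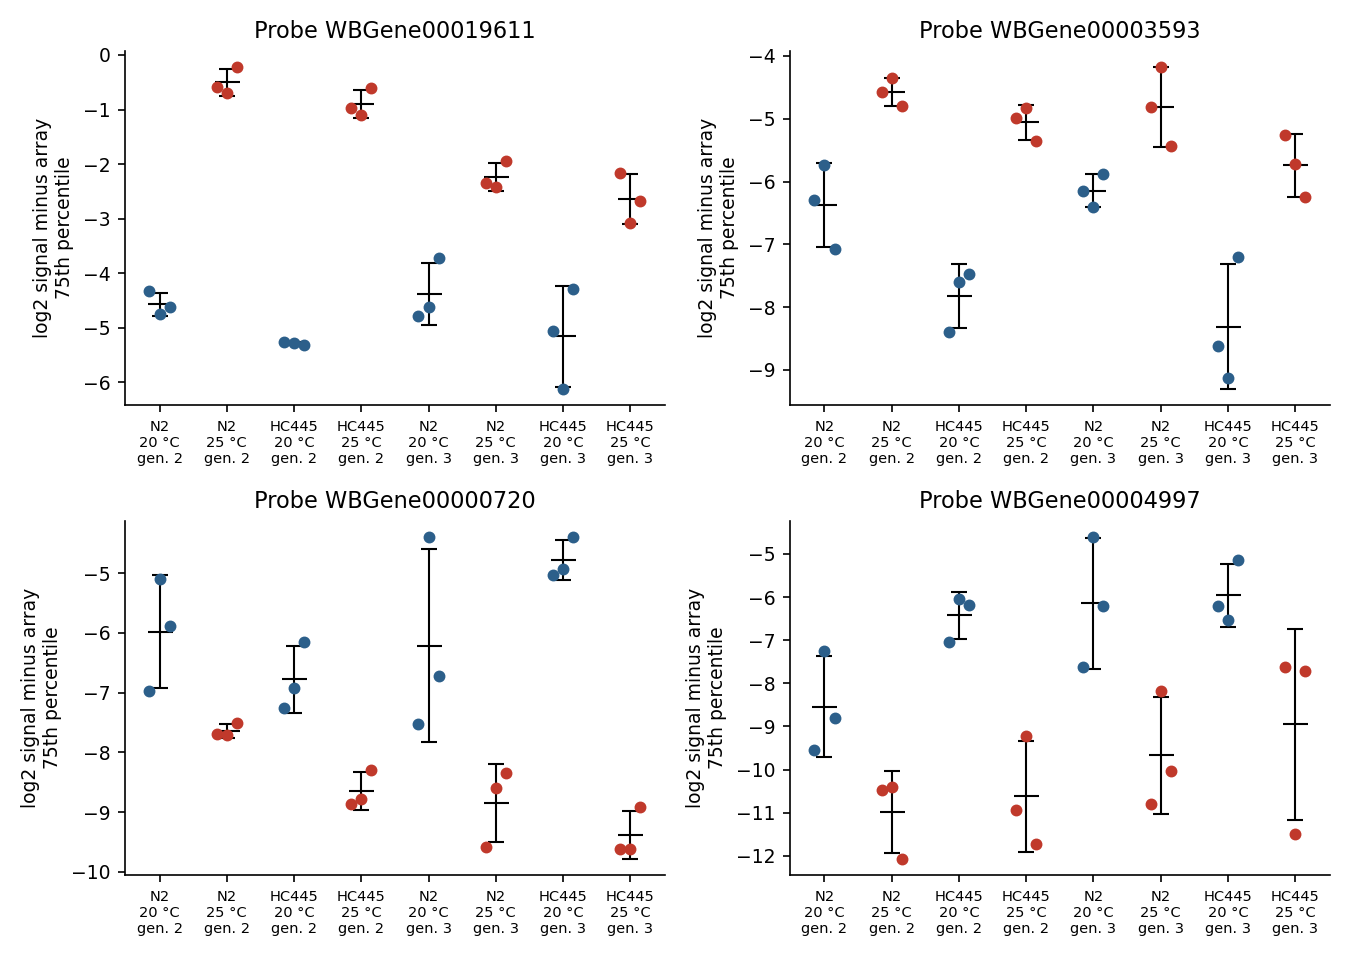
Normalised log2 signal, relative to the 75th percentile of each array, of the 2 probes that rose most and the 2 that fell most after 25 °C grandparents, in the 8 groups of 3 arrays (dots, blue for 20 °C and red for 25 °C ancestors; bars, mean ± SD). Generation 2 shows the temperature of the mothers and generation 3 that of the grandparents, and WBGene00019611 had means of -0.50 and -2.24 in the N2 25 °C groups of generations 2 and 3, against -4.57 and -4.38 in their controls.

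The grandparental set was small and its size moved with the processing. It held 19 genes (7 higher, 12 lower) with quantile normalization and 18 with the deposited values, 71 with the scan day as a block, 70 with slide as a random block, 1 (higher) with slide as a fixed block, and 7 (3 higher, 4 lower) without the arrays that carry a spike-in note. Within the scan days the 33 genes kept their sign for 32 of 32 with a value in replicate 1, 32 of 32 in replicate 2 and 33 of 33 in replicate 3, and on the only slide with both temperatures of one strain in generation 3 for 32 of 33. These genes were picked on the same arrays. Picked without the arrays of replicate 3, 7 genes passed (4 higher, 3 lower), and all 7 moved the same way on the arrays of replicate 3, with a median of 1.45 on the log2 scale. Among generation 3 arrays, the count was 12 without the N2 20 °C array of replicate 2, 18 and 15 without the N2 25 °C arrays of replicates 1 and 2, 14 without the HC445 20 °C array of replicate 1 and also without that of replicate 3, and 13 and 11 without the HC445 25 °C arrays of replicates 2 and 3. Among generation 2 arrays, which enter through the shared spread, it was 51 without the N2 20 °C array of replicate 3 and 21 without the HC445 20 °C array of replicate 2.

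In N2 alone 13 genes passed for grandparental temperature (2 rose, 11 fell), and in HC445 alone 10 genes (3 rose, 7 fell). The N2 count was 1 (higher) with quantile normalization and with the deposited values, 2 (1 higher, 1 lower) without the scan day of replicate 3, and 0 with slide as a fixed block, without slide 9 and without the arrays with a spike-in note. The HC445 count was 10 with quantile normalization and with the deposited values, 1 (higher) with slide as a fixed block, 3 (all higher) without the scan day, 5 (2 higher, 3 lower) without slide 9 and 3 (all lower) without the noted arrays. Of the 13 genes, 12 moved the same way in HC445, with a median of 0.63 on the log2 scale in the direction of the N2 change, and all 10 HC445 genes moved the same way in N2, with a median of 1.73. The difference between the strains (strain by grandparental temperature) had a median SE of 0.44 on the log2 scale. No gene passed its limma test, and 257 had an unadjusted p under 0.05. With slide as a fixed block, which left 3 residual degrees of freedom, 18 genes passed it, all with a negative difference (HC445 minus N2). Across genes the fold changes of the strains had an r of 0.19, and effects taken from different scan days had r between -0.13 and 0.27. With the scan day as a block the counts were 27 and 17. The N2 count was 57, 0 and 2 without the 20 °C arrays of replicates 1, 2 and 3, and 1 without the 25 °C array of replicate 1 or of replicate 2. The HC445 count was 6, 5 and 6 without the 20 °C arrays of replicates 1, 2 and 3, and 5 without the 25 °C array of replicate 1 or of replicate 2.

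The effects of the 2 generations were then set against each other. All 6 genes that rose after 25 °C grandparents had also risen after 25 °C mothers, where independent lists would share 0.33, and 12 of the 27 genes that fell had also fallen after 25 °C mothers, where independent lists would share 2.30 (one-sided Fisher's exact test, p = 2.56e-08 and p = 7.17e-07; genes are not independent, and these p-values treat them as such). Slide 9 held 25 °C arrays of both generations and no 20 °C array, so a slide effect could move both comparisons the same way. Both comparisons also share the estimate of the spread per gene. The overlap alone therefore does not show a carry-over. Another 4 genes went the opposite way, with a median log2 fold change of 1.61 after 25 °C mothers and -1.27 after 25 °C grandparents, and 11 genes passed for the grandparents alone. Most of the parental effect was gone in generation 3. The 634 genes that rose after 25 °C mothers had a median log2 fold change of -0.01 after 25 °C grandparents, and the 992 genes that fell had one of -0.06. The difference between the effects (parental minus grandparental) passed the threshold for 617 genes, 308 positive and 309 negative, and 583 of them were among the 1626 parental genes. WBGene00001557 had a difference of 6.76 ± 1.14 (SE, log2 scale; limma adjusted p = 0.000743), with 3 of its 6 arrays of 20 °C mothers well above background, and WBGene00016356 one of -4.14 ± 0.77 (limma adjusted p = 0.00173), with 4 of its 6 arrays of 25 °C mothers well above background. WBGene00012176 (limma adjusted p = 3.65e-06) had a positive and WBGene00010423 (limma adjusted p = 0.00183) a negative difference, but no array of 20 °C mothers for the former or of 25 °C mothers for the latter was well above background, so no size is given. With the scan day as a block 1198 genes passed, with slide as a random block 1191 and with slide as a fixed block 47.

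**Figure D2:**
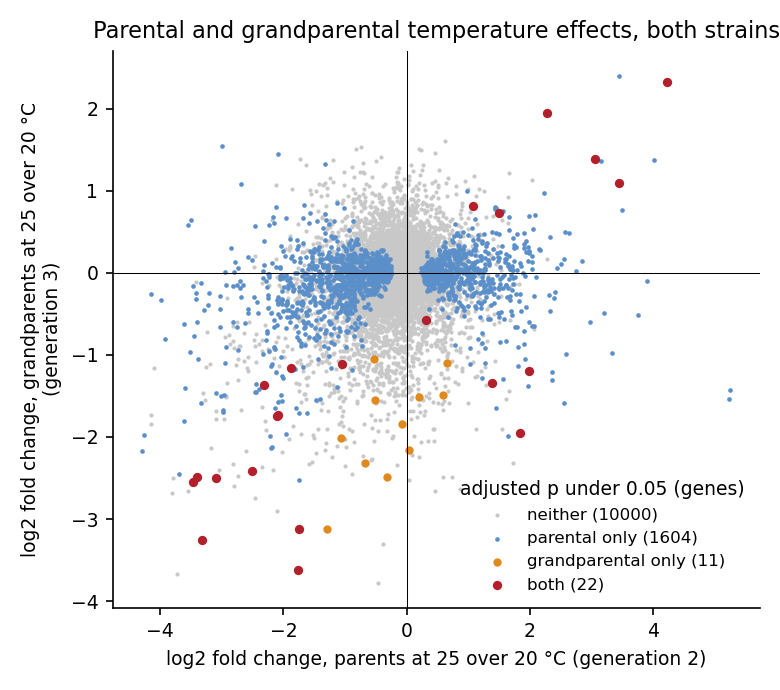
Log2 fold change of each of 11637 genes after 25 °C over 20 °C mothers (generation 2, x axis) against that after 25 °C over 20 °C grandparents (generation 3, y axis), both strains together. Colours mark genes past an adjusted p of 0.05 in neither comparison (10000), for the parents alone (1604), for the grandparents alone (11) and for both (22, of which 18 went the same way).

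A single score per array, the mean log2 signal of the 634 genes that rose after 25 °C mothers minus that of the 992 genes that fell, each gene centred on its mean over the arrays, summarised what was left in generation 3. It was -0.42 ± 0.10 (SD, n = 6) after 25 °C grandparents and -0.57 ± 0.07 (SD, n = 6) after 20 °C grandparents, a difference of 0.16 (exact permutation test, two-sided, p = 0.0173). The difference in generation 2, where the genes had been chosen, was 2.22, of which 0.16 is 7.01%. With genes chosen in N2 and scored in HC445, which avoids that choice, the generation 3 difference was 10.4% of that in generation 2, and with genes chosen in HC445 and scored in N2 it was 5.75%. Within each strain the groups of 3 allow no exact p below 0.10. Arrays of one strain and scan day gave a positive difference in 5 of 6 pairs (exact sign-flip test, two-sided, p = 0.0625), and without the arrays of replicate 3 the difference was 0.15 (exact permutation test, p = 0.0857). Across all genes the parental and grandparental fold changes had a Pearson r of 0.23, and effects from different scan days had r between 0.00403 and 0.24.

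**Figure D3:**
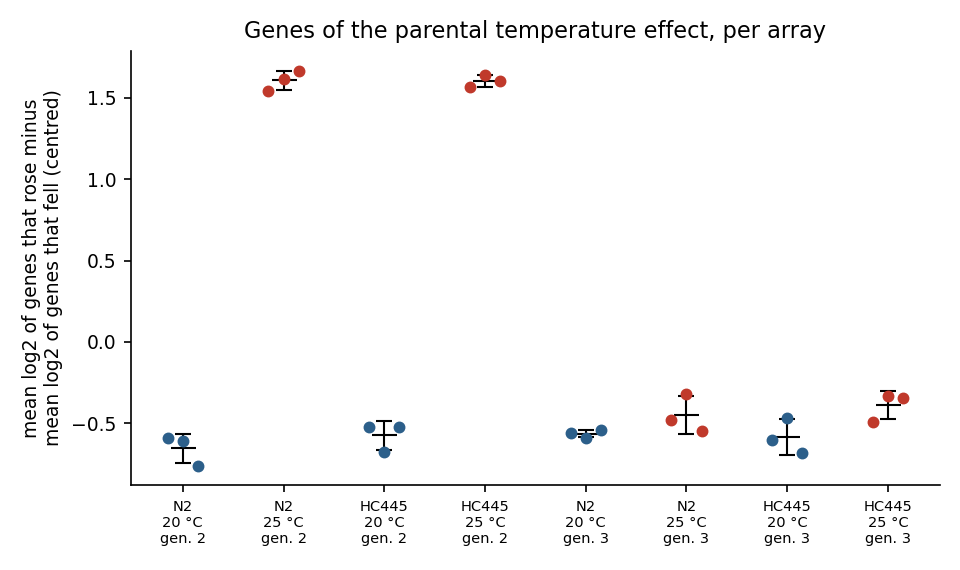
Score of the parental temperature genes (mean log2 signal of the 634 genes that rose minus that of the 992 that fell, centred per gene) for each of the 24 arrays by group (dots, blue for 20 °C and red for 25 °C ancestors; bars, mean ± SD). The 25 °C arrays of generation 2 lay between 1.54 and 1.66, and all 12 generation 3 arrays between -0.68 and -0.32.

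The strains were compared in the 20 °C groups of both generations. The strain difference was narrow and consisted mainly of lower signals in HC445. In HC445 13 genes differed from N2 (limma, Benjamini-Hochberg), of which 1 was higher and 12 lower. WBGene00004795 had a log2 signal of -6.37 ± 0.32 (SD, n = 6) in HC445 and -1.23 ± 0.58 (SD, n = 6) in N2, 35.2-fold lower (limma adjusted p = 5.50e-12), and WBGene00001816 had -4.58 ± 0.46 against -0.83 ± 0.23, 13.5-fold lower (limma adjusted p = 5.50e-12). WBGene00009453 was the gene that was higher, with a log2 fold change of 1.56 ± 0.20 (SE; limma adjusted p = 0.000269). For these 3 probes no HC445 array overlapped any N2 array among all 24, the 25 °C groups included. Because the probe IDs carry no gene names here, the probes of sid-1 and haf-6 were not singled out. The count was 30 with the scan day as a block, 18 and 3 with slide as a random and as a fixed block, 6 without the arrays with a spike-in note, 8 without the HC445 generation 2 array of replicate 1 and 21 without the N2 generation 3 array of replicate 1. The 13 genes had the sign of the pooled fit on 11 of 11 values within replicate 1, 13 of 13 within replicate 2 and 12 of 12 within replicate 3, the arrays on which they were picked. Picked without the arrays of replicate 3, 7 genes passed, and 6 of the 6 with a value had the same sign on the arrays of replicate 3.

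**Figure D4:**
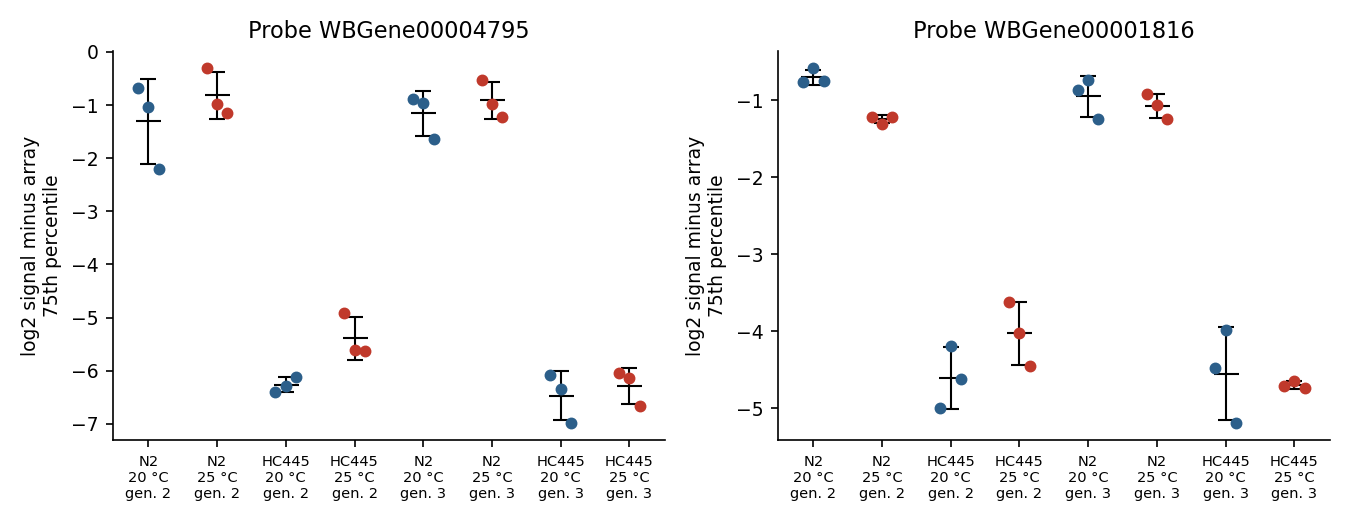
Normalised log2 signal, relative to the 75th percentile of each array, of the 2 probes with the largest strain difference in the 8 groups of 3 arrays (dots, blue for 20 °C and red for 25 °C ancestors; bars, mean ± SD). All 12 HC445 arrays lay between -6.98 and -4.92 for WBGene00004795 and between -5.19 and -3.62 for WBGene00001816, below all 12 N2 arrays of each.

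The control groups of generations 2 and 3, both kept at 20 °C, were compared as a measure of change with no temperature treatment. No gene passed the threshold (limma, Benjamini-Hochberg; smallest adjusted p = 0.594), and 366 genes had an unadjusted p under 0.05, against 581.85 expected. With the scan day as a block no gene passed, and the fold changes of different scan days had correlations across genes of -0.01, -0.19 and 0.31.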

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

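The tests of slide 9, of the scaling and of the background were chosen after the results were seen. Single outlying samples were not tested within groups of 3. By array quality weights, estimated over all 24 arrays, the N2 20 °C generation 2 array of replicate 3 stood apart at 0.277, the next lowest being 0.651. The effect of temperature differed between the generations: 617 genes passed the test of the parental minus the grandparental effect, which is an interaction within the fit. Among the 1626 parental genes 583 passed it, 574 of them with the larger change in generation 2. These 1626 were chosen for their change on the same generation 2 arrays, which favours both of these counts. A signal outside the compared probes also stood apart. The added spike-in RNA was 5.30 times brighter (ratio of medians) on the 6 arrays with a note on its concentration than on the 18 others, with medians of 222871 and 42020. The array whose note is only a suspicion, from HC445 at 20 °C in generation 2, read 176253, above the 64840 of the brightest array without a note, and 5 of the 6 noted arrays were 25 °C arrays.

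The 33 genes of the grandparental effect are the pattern a biologist would most want to follow up. Only 1 slide held both temperatures of a strain in generation 3, so the other comparisons ran across slides. In replicate 3 both 25 °C arrays were on slide 9, the only slide weighed here. With slide as a fixed block, which left 3 residual degrees of freedom, 1 of the 33 genes stayed called, so effects of other slides stay open. Without slide 9, 8 genes were called, all 8 among the 33, so slide 9 cannot be the whole source of those 8. The other 25 had a median change of 1.55 in the called direction (log2 scale, median SE 0.31) with all arrays and of 1.64 (median SE 0.35) without slide 9. Their change was thus not smaller without slide 9, and their calls ended with a larger SE and 12 in place of 16 residual degrees of freedom. For each of the 25 the change without slide 9 was at least 0.87 of that with all arrays. Within scan days their median change was 1.15 in replicate 1, 1.75 in replicate 2 and 1.47 in replicate 3, the only one with slide 9. These values argue against slide 9 as the whole source of the 25. However, these 25 were chosen on all arrays, those outside slide 9 included, which raises all these medians. How much of the change comes from that choice stays open. Scaling is no whole cause for the 17 genes that stayed called with quantile normalization. The other 16 all kept their direction, with a median change of 1.70 (median SE 0.35) before and of 1.503 (median SE 0.36) with quantile normalization, so a difference between these 2 scalings cannot be their whole cause either, and their calls ended with a smaller change and a larger SE. Dim signal is no whole cause for the 21 genes called among probes well above background on all arrays, and it stays open for the other 12. An effect of grandparental temperature itself, which the design names, stays open as a hypothesis, and so does a difference in collection time or handling between treated and control cultures, which was not tested.

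More genes fell than rose after 25 °C mothers, with 39.0% rises among the calls. With quantile normalization the rises were 55.5% of the calls, so the scaling may account for the direction of the imbalance. Leaving out 1 array, the N2 20 °C generation 2 array of replicate 3, gave 47.3% and, in N2 alone, 55.0%, so the imbalance is not tied to the scaling alone. Slide as a fixed block gave 70.7%, but of only 41 calls, and slide as a random block gave 39.6%. The genes themselves did not turn: 628 of the 634 rises and 703 of the 992 falls stayed called in their direction. Whether embryos of 25 °C mothers held less mRNA of many kinds stays open, since the arrays measure signals relative to the rest of the array.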

How the results depend on the processing

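The alternatives without slide 9 and without the scan day of replicate 3 were chosen after the data were examined. Of 529 values of named probes under the alternatives 474 stayed past the threshold, 55 fell short of it and none changed sign. The balance of parental calls in both strains (634 higher, 992 lower) did turn, to 936 and 752 with quantile normalization, 910 and 710 with normexp, 937 and 756 with the deposited values and 29 and 12 with slide as a fixed block, and that of the grandparental calls (6 higher, 27 lower) to 4 and 3 without the scan day of replicate 3 and to 1 and 0 with slide as a fixed block. Counts are in the order both strains, N2, HC445. The parental counts (1626, 636, 591) became 41, 314 and 2 with slide as a fixed block, which leaves 3 residual degrees of freedom, 2666, 1293 and 1130 with the replicate block, 852, 150 and 163 without the 6 arrays with a spike-in note, and 973, 287 and 333 without the scan day of replicate 3. With slide as a random block the N2 count was 1419, with array quality weights the HC445 count was 896, and without slide 9 the single-strain counts were 373 and 375. The grandparental counts (33, 13, 10) became 1, 0 and 1 with slide as a fixed block, 71, 27 and 17 with the replicate block, 7, 0 and 3 without the noted arrays, 7, 2 and 3 without the scan day, 8, 0 and 5 without slide 9, and 21, 6 and 6 on probes well above background on all arrays. The count for both strains was 20 with normexp, 19 with quantile normalization, 18 with the deposited values, 70 with slide as a random block and 72 with array weights. The N2 count was 1 with quantile normalization and with the deposited values, and the HC445 count was 20 with slide as a random block and 16 with array weights. The parental minus grandparental count (617) became 47 with slide as a fixed block, 1191 with it as a random block, 1198 with the replicate block, 171 without the noted arrays, 284 without the scan day and 321 without slide 9. The strain count (13) became 3 with slide as a fixed block, 30 with the replicate block, 6 without the noted arrays and 7 without the scan day. With slide as a fixed block 1 gene passed for strain by parental temperature, 18 for strain by grandparental temperature and 1 for generation at 20 °C, each 0 otherwise. What caused these changes was not tested.

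Leaving out each array in turn gave 1278 to 1636 genes for parental temperature in both strains, 461 to 648 in N2 and 356 to 697 in HC445, 11 to 51 for grandparental temperature in both strains, 0 to 57 in N2 and 5 to 14 in HC445, 529 to 764 for the parental minus grandparental effect, 8 to 21 for strain, and 0 to 0 for the interactions with strain and for generation. The correlation across genes of the parental and grandparental fold changes ran from 0.16 to 0.28. Arrays with one replicate number deviated together, with a mean correlation of deviations of 0.20 over 84 pairs of arrays. Pairs with other numbers had -0.10. Deviations were taken from the mean of each group of 3 arrays, so this second value largely follows from the first and is no separate comparison. Of the 84 pairs, 66 were over 0.1 and the lowest was -0.24, so the numbers were taken to mark a scan batch and not matched samples. The main fit holds no term for that batch, so the main counts ignore it. The replicate block was run only as an alternative, with 2666 in place of 1626 parental and 71 in place of 33 grandparental genes in both strains. All 24 arrays correlated best with their own number. The replicate block kept all 33 grandparental and all 1626 parental calls and turned no other call, and the counts of 0 stayed at 0 under it. The mean over several probes of a gene was not run, since each gene had 1 probe, and the gene lists were not tested for lack of gene names. Dim signal limits the low level class of genes most, where the median standard error of the grandparental log2 fold change was 0.48, against 0.22 in the middle and 0.11 in the high class.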

Other observations

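The tests of the score and the exchange of arrays within scan days in this part were chosen after the results were seen. What is left of the parental change in generation 3 was scored over all genes that had passed for the parents. The score of the parental genes differed by 0.16 between 25 °C and 20 °C grandparents, and without the 22 parental genes that also passed for the grandparents it differed by 0.12 (exact permutation test, two-sided, p = 0.0411). That test ignores the scan day. In the 6 pairs of arrays of one strain and day the sign-flip p was 0.0625 with and without those genes, where 0.0313 is the smallest possible. Without those genes 73.7% to 82.7% of the mean difference of the pairs was left, leaving out each pair in turn, but the 95% t interval of what was left over all 6 pairs, -0.00466 to 0.25, included 0, so whether the part outside those genes exceeds chance stays open. With quantile normalization the difference was 0.15 (exact permutation test, p = 0.0130; sign-flip p = 0.0313, and 0.0625 without those genes). Which side carried it depended on the scaling: the mean over the 992 genes that fell differed by -0.18 (exact permutation test, p = 0.0238) and over the 634 that rose by -0.03 (p = 0.325), against -0.06 and 0.08 with quantile normalization. With genes chosen and scored without replicate 3, and so without slide 9, the difference was 0.14 with an exact permutation p of 0.0857, where 0.0286 is the smallest these 8 arrays allow. All 4 pairs of replicates 1 and 2 were positive, and the 95% t interval of their mean was -0.06 to 0.33 with these genes and 0.02 to 0.28 with the genes chosen on all arrays. The 2 pairs of replicate 3, with their 25 °C arrays on slide 9, differed, with 0.34 in HC445, the highest of the 6 pairs, and -0.0007 in N2. No array of slide 9 is in the 4 pairs of replicates 1 and 2, so slide 9 cannot be the source of their difference. That difference was 0.14 or 0.15 with the 2 choices of genes, close to the 0.16 of all arrays. As only 1 of the intervals for replicates 1 and 2 leaves out 0, whether it exceeds chance stays open. A weak broad carry-over is therefore a hypothesis. The strains' differences did not separate (exact permutation test of N2 against HC445, p = 0.50, with 0.10 the smallest possible).

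The correlation across all genes does not add to this. The parental and grandparental fold changes correlated at r = 0.23, but 19 of 100 splits of the generation 3 arrays gave an r at least as far from 0, the highest 0.34. Those splits exchange arrays across scan days. With arrays exchanged only within strain and scan day, 9 of 32 splits gave an r as far from 0, the highest other 0.32, so chance cannot be excluded for it either way.

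Other splits of the same arrays, which also exchange arrays across scan days, were refitted for the counts as well. For parental temperature in both strains, 1626 genes stood against at most 344 in the other splits. For grandparental temperature in both strains, 33 stood against at most 2. In each of these 2 cases the real split was the only 1 of 100 to give as many. Arrays of one scan day deviated together, and exchange within days was not run for the counts, so these splits alone do not exclude chance. For the difference between these effects, 617 genes stood against at most 18, again only 1 of 100. These splits exchange the temperatures in both generations and so remove the parental effect too. They therefore cannot show whether the 2 effects differ by more than chance. For strain at 20 °C, 2 of 100 splits, the real one included, gave 13 genes or more. The highest other gave 27 and put all 4 arrays of replicate 2 on one side, which follows a scan day, and with the scan day as a block the strain count was 30. The single-strain comparisons have 10 splits each, too few for a share under 0.05. Their other splits gave at most 0 genes, against 636 and 591 for parental and 13 and 10 for grandparental temperature in N2 and HC445. For the 3 comparisons without a call, all 100 splits gave as many. Their highest others were 1626 for strain by parental temperature and 33 for strain by grandparental temperature, from splits that exchange the temperatures within one strain and so turn the interaction into the temperature effect, and 36 for generation at 20 °C, from a split that put all 4 arrays of replicate 2 on one side.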
